A study of Homo sapiens with 10 samples.

How the data were processed

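The samples were biopsies of bronchial epithelium from 5 subjects, each sampled before and after an allergen was applied to a segment of the airway through a bronchoscope. Total RNA was extracted on spin columns, biotin-labelled and hybridised to Affymetrix oligonucleotide arrays, 1 array per sample, per the labels. The 10 arrays form 5 before and after pairs, numbered 1, 2, 3, 5 and 6 here. The time between the challenge and the biopsy after it, and any biopsy of a segment given diluent alone, are not given in the sources used here.

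The deposited values are 1 intensity per probe set and array, on a linear scale. They were summarised by the authors with MAS5, per the submitters' processing notes, with no version or scaling target given in the sources used here. The values were not on a common scale between arrays: after trimming 2% at each end, the mean intensity per array ran from 41.8 to 243, a 5.82-fold range. No detection calls were used. The number of arrays limits the precision of every value.

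Each array was scaled to the same 2% trimmed mean of 78.7, the geometric mean of the 10. The scaled intensities were put on a log2(signal + 8) scale. The pseudocount of 8 was the power of 2 nearest the 20th percentile of all deposited values, which was 7.1. A change on this scale understates the change of genes with low signal.

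The table held 12625 probe sets, of which 67 were Affymetrix controls. In the platform annotation, 10943 of the others had 1 gene symbol, 545 had several and 1070 had none, and only those with 1 symbol were named. The gene numbers of 10934 of them were found in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. That table was used for names only, since no genome build is named for the array, so no coordinates are given. Left out of every step were 27 probe sets, those of XIST and of genes the table places on the Y chromosome. Each of the remaining 8200 genes was represented by its probe set with the highest mean log2 signal over the 10 arrays. Genes with a mean log2 signal below 4.86, the 40th percentile of all probe sets other than controls, were left out, and 5531 genes were tested.

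After against before challenge was tested with limma 3.58.1 in R 4.3.3, using lmFit with the subject as a block and eBayes with an intensity trend, two-sided. Adjusted p-values follow Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are limma's moderated standard errors over the 5 pairs unless named as SD. The pairing comes from the subject numbers in the sample titles. As a check, the correlation of deviations from the group means between the 2 arrays of a subject was 0.22, 0.23, 0.23, 0.57 and 0.44 for pairs 1, 2, 3, 5 and 6, and each array correlated best with its own partner.

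Before the data were examined, 41 gene lists were fixed, 19 of cell type markers and 22 of programmes. The 34 lists with 5 or more tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, which compares the list's genes with all other genes. Camera was run again with the correlation estimated from the data. For the fits with a random block, without trend and with robust eBayes, which camera does not take, the lists were tested with cameraPR on the moderated t of the fit, which gave camera's p-values for the fit used here. Fry asked whether a list's genes moved, on balance, one way, without comparing them with other genes. For each list, calls of single genes are given over all genes tested and adjusted over the list alone. Of the genes on these lists, 16 are on 2 lists, among them S100A8 and S100A9, which are on the neutrophil and the antimicrobial lists, and VEGFA, which is on the matrix and the hypoxia lists.

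The rule for named genes was also fixed before the data were examined. In each direction it took the 12 genes with the largest mean change among those called and changed the same way in all 5 pairs, and for each list up to 3 members with the smallest unadjusted p. Any other gene named in the text was chosen after its values were seen. RNA quality was measured by the log2 ratio of the 3' to the 5' control probe set of GAPDH and ACTB, compared over the 32 sign flips of the 5 paired differences in an exact permutation test.

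The alternatives fixed before the data were examined were: no block, the subject as a random block, pseudocounts of 1 and 32, quantile normalization, median scaling, no filter, a filter at the 60th percentile, all probe sets, the mean of a gene's probe sets, no probe sets with the suffixes _x_at and _s_at, eBayes without trend, robust eBayes, array weights, an estimated inter-gene correlation, and leaving out each pair. The fits on pairs 1, 2 and 3 alone, on pairs 5 and 6 alone, and with the GAPDH ratio as a covariate were added after seeing the data. So were 6 further gene lists, 4 of them tested and adjusted over 38 lists with the 34, of macrophages and lysosomes, clock genes in phase and in antiphase with DBP, actin and serum response factor, the ATF4 response and cholesterol synthesis. With only 2 pairs, the p-values of the fit on pairs 5 and 6 alone rest mostly on the variance that eBayes pools over genes. They say little about the spread of each gene between subjects. Outlying samples were sought with Dixon's test, and the arrays were also split in 100 ways with a fixed seed.

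The test was tested on simulated data with known answers. In 20 simulations of the 5531 genes with 200 of them changed, it recovered 68.9% of the genes changed by 1 on the log2 scale and 95.6% of those changed by 2, all called genes with a true change had the right sign, and 4.84% of calls were false. With no effect it called 0 genes and 0 lists. The simulated noise was independent between genes, so this says nothing about lists of correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.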

Results

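Gene expression was measured in biopsies of bronchial epithelium, the cell layer that lines the airways, taken from 5 subjects before and after segmental allergen challenge. In this procedure an allergen is placed in a segment of the lung through a bronchoscope. The series asks how allergen challenge alters gene expression in the airway epithelium. There were 5 arrays before and 5 after challenge, and each subject supplied both. A biopsy also holds cells other than epithelium, so markers of other cell types were measured alongside.

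The arrays differed in brightness, with pairs 1, 2 and 3 dimmer and pairs 5 and 6 brighter. The trimmed mean intensity was 41.8 on the dimmest and 243 on the brightest array before scaling. The array after challenge was the brighter of its pair in 3 pairs and the dimmer in 2, and the mean log2 difference was 0.23 ± 0.43 (SD, n = 5 pairs; exact permutation p = 0.25). The log2 ratio of 3' to 5' GAPDH signal was 1.21 ± 0.44 before and 1.30 ± 0.34 after challenge (SD, n = 5; exact permutation p = 0.75). For ACTB it was 1.45 ± 0.40 before and 1.38 ± 0.47 after (SD, n = 5; exact permutation p = 0.94). The smallest p that 5 pairs allow is 0.0625, so these tests could not reach 0.05.

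After challenge, the genes called higher included cytokine and chemokine genes, and those called lower included the macrophage genes GPNMB, VSIG4 and CD68. IL1RN, the interleukin-1 receptor antagonist, rose 10.6-fold, by 3.40 ± 0.56 on the log2 scale (SE, n = 5 pairs; adjusted p = 0.0167). A second IL1RN probe set, with a mean signal below the filter, gave 0.17, and with the mean of both the log2 change was 1.79 (adjusted p = 0.0389). CXCL8, the neutrophil chemokine interleukin-8, rose 7.18-fold, by 2.84 ± 0.27 (adjusted p = 0.00333). IL1B, the cytokine interleukin-1 beta, rose 5.75-fold, by 2.52 ± 0.33 (adjusted p = 0.00735). G0S2, an inhibitor of triglyceride breakdown, rose 7.91-fold, and CD55, which protects cells from complement, rose 5.87-fold. In total, 88 genes were higher and 21 lower of the 5531 tested with limma.

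Among called genes that were higher in all 5 pairs, the 12 largest increases also included the protease gene MMP10 (log2 change 2.16), the transcription factor MAFF (2.08), S100A8 (2.08) and S100A9 (1.90), which encode the subunits of calprotectin, GPRC5A (1.88), the retinoic acid-producing enzyme ALDH1A3 (1.85) and TM4SF1 (1.80). Their adjusted p-values from limma ran from 0.00333 for GPRC5A to 0.0148 for S100A9, and TFF1, higher in 4 pairs, lay outside this ranking at 1.85. Pair 6 had the smallest change for 11 of the 12, and for GPRC5A pair 3 did.

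GPNMB, a glycoprotein abundant in macrophages, fell by 1.93 ± 0.38 on the log2 scale (SE, n = 5 pairs; limma adjusted p = 0.0399), and was 3.81-fold higher before challenge. VSIG4, a complement receptor of tissue macrophages, fell by 1.39 ± 0.28 (adjusted p = 0.0421). The macrophage lysosomal protein gene CD68 fell by 0.95 ± 0.20 (adjusted p = 0.0490). DDIT4, an inhibitor of mTOR signalling, fell by 1.44 ± 0.21 (adjusted p = 0.0140), and TSC22D3, a glucocorticoid-induced gene, by 1.07 ± 0.17 (adjusted p = 0.0167). KRT15, a keratin of basal cells, fell by 1.29 ± 0.22 (adjusted p = 0.0198), but was at -0.58 in pairs 5 and 6 alone (0.244). The clock-controlled transcription factor DBP fell by 1.32, RBP4, a retinol carrier, by 1.14 (0.64 with a pseudocount of 32), the alcohol dehydrogenases ADH1A and ADH7 by 0.96 and 0.93, the lysosomal enzyme HEXA by 0.98 and GCHFR, a regulator of GTP cyclohydrolase, by 0.91. These 12 had the largest decreases among called genes lower in all 5 pairs; APOE, a lipid carrier abundant in macrophages, fell by 3.01 but in 4 of 5 pairs (adjusted p = 0.0486). With the mean of a gene's probe sets, the log2 change was -0.22 for HEXA (adjusted p = 0.590) and -0.58 for ADH1A (0.106). TSC22D3 (0.0655), DBP (0.0527), CD68 (0.0524), DDIT4 and VSIG4 (0.0507 each) also lost their calls there. APOE was not called without pair 1 (0.0942), 2 (0.176), 5 (0.151) or 6 (0.0742). The ADH1A probe set belongs to a gene family and can cross-hybridise, and both other probe sets of HEXA gave log2 changes above 0, at 0.28 and 0.03.

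**Figure D1:**
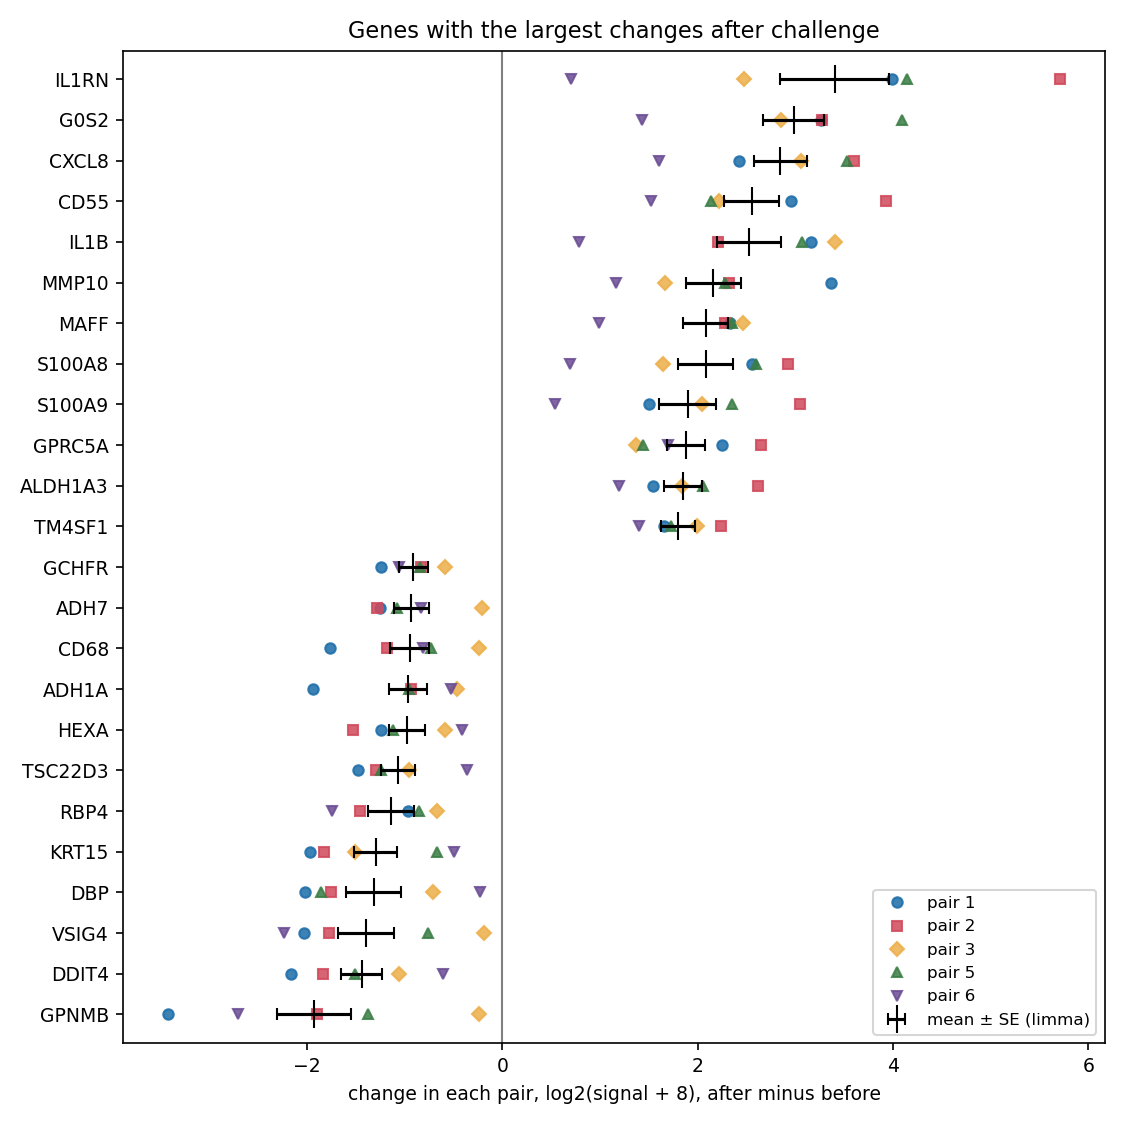
Change of the 12 genes with the largest increase and the 12 with the largest decrease (limma, called and the same way in all 5 pairs). Each point is 1 pair, on a log2(signal + 8) scale after minus before; black bars are the mean ± SE. The points of all 24 genes lie on one side of 0, and the means run from 3.40 for IL1RN to -1.93 for GPNMB.

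**Figure D2:**
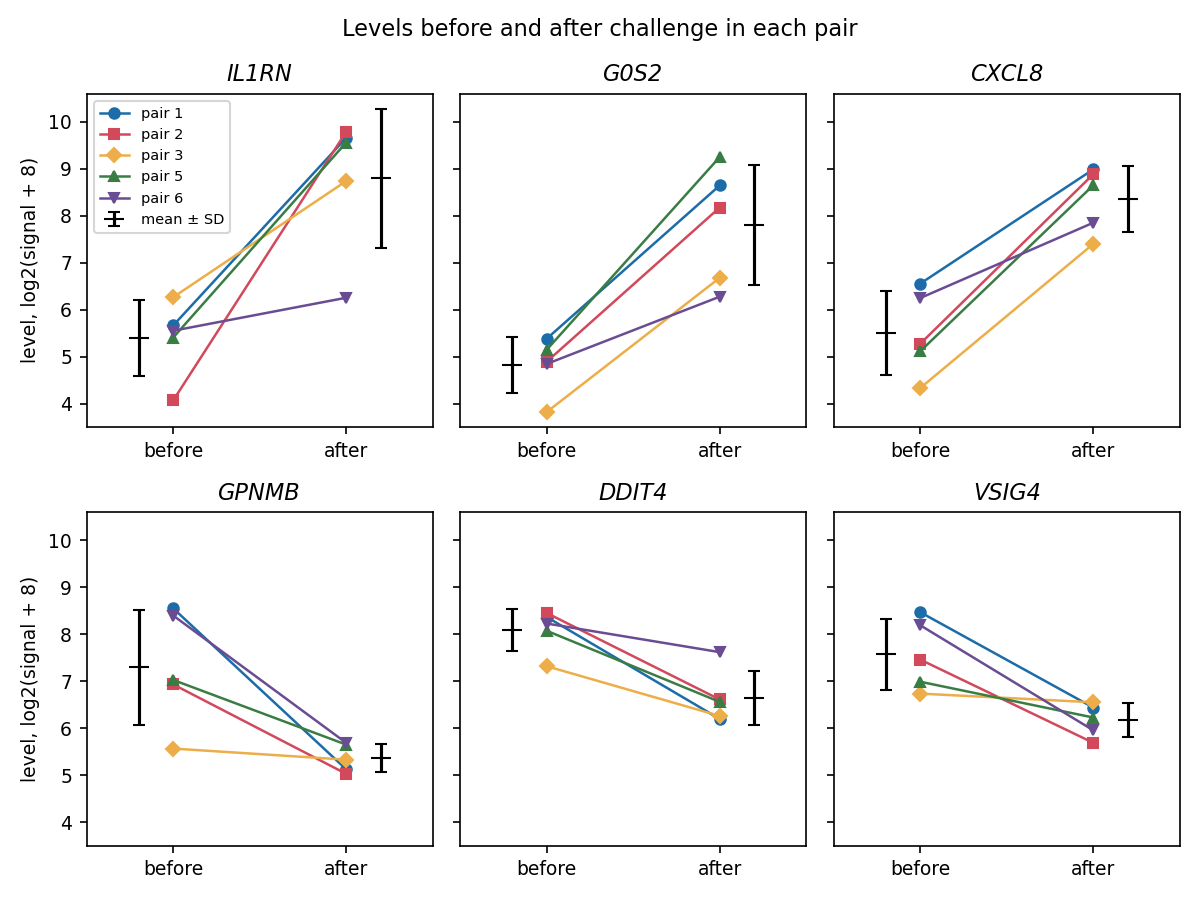
Levels in each pair, log2(signal + 8), of the 3 genes with the largest increase and the 3 with the largest decrease among called genes changed the same way in all 5 pairs; each line joins the 2 arrays of a pair, and black bars are the group mean ± SD. IL1RN went from 5.40 ± 0.81 to 8.80 ± 1.48 and GPNMB from 7.30 ± 1.22 to 5.37 ± 0.30.

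At a looser adjusted p of 0.10 limma called 228 genes, and at an unadjusted p of 0.05, 486 genes were higher and 459 lower. The count of 109 changed genes depended on single pairs: it was 10 without pair 5, 25 without pair 1 and 28 without pair 2, and it was 31 without the subject block, 33 without the intensity trend, 67 with the mean of a gene's probe sets, 70 without the filter and 40 in pairs 1, 2 and 3 alone. G0S2, CXCL8, CD55, MAFF, GPRC5A, ALDH1A3 and TM4SF1 were called whichever pair was left out. Without pair 5 the adjusted p was 0.0869 for IL1RN, 0.0507 for IL1B, MMP10 and S100A8, and 0.0810 for S100A9. IL1RN also missed the threshold without pair 1 (0.0639) and without pair 2 (0.0541). None of the 12 named lower genes was called without pair 2 (adjusted p from 0.0541 for DDIT4 to 0.187 for DBP) or without pair 5 (from 0.0507 for KRT15 to 0.185 for DBP). Without pair 1 only DDIT4 of the 12 was called, the others lying between 0.0617 for ADH1A and 0.152 for DBP. Without pair 3 the calls of DBP (0.0750), KRT15 (0.0655), RBP4 (0.0615) and ADH1A (0.0521) were lost, and without pair 6 those of GPNMB (0.0806), VSIG4 (0.0846), RBP4 (0.124), CD68 (0.0790) and ADH7 (0.0632).

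Genes of the NF-kB response and chemokines that attract neutrophils were higher after challenge. Of 17 tested members, 5 rose, 0 fell and 12 did not pass the test; adjusted over the list alone, 11 rose. CXCL8, IL1B and IL1RN led the list. Its median log2 change was 0.91, its mean was above 0 in 5 of 5 pairs, and camera called it at the preset correlation (adjusted p = 9.66e-10; adjusted p = 0.364 with an estimated correlation, where the call was lost; fry adjusted p = 0.0940). In pairs 5 and 6 alone the median was 0.49. No list was called with an estimated correlation, and the lowest such p was 0.0772, for the immediate early genes. Of the 11 lists that camera called at the preset correlation, fry called only the immediate early genes; its adjusted p for the other 10 ran from 0.0619 for the unfolded protein response to 0.163 for club and secretory cells.

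Markers of neutrophils were also higher as a list. Of 12 tested neutrophil genes, 2 rose, S100A8 and S100A9, and 10 did not pass; adjusted over the list alone, 5 rose. BCL2A1, a survival gene of leukocytes, had a log2 change of 1.18 (adjusted p = 0.0650). The median log2 change was 0.52, with the list's mean above 0 in 5 of 5 pairs (camera adjusted p = 5.50e-04; adjusted p = 0.364 with an estimated correlation; fry adjusted p = 0.142). Without S100A8 and S100A9 the median of the other 10 genes was 0.24, with a 95% bootstrap interval of -0.10 to 0.92, and with the filter at the 60th percentile the list's median was 0.12. S100A8 and S100A9 are also made by airway epithelium under stress, and they are the 2 called genes of the antimicrobial and acute phase list, of which 11 did not pass (2 rose adjusted over the list alone; median 0.16, camera adjusted p = 0.158). CP, the copper carrier ceruloplasmin, was the next member at 0.37 (adjusted p = 0.235). This list was called without pair 5 (adjusted p = 0.0494), without the filter (0.0434) and in pairs 1, 2 and 3 alone (0.00942). Without pair 1 its median was -0.01 (0.252), and in pairs 5 and 6 alone it was -0.12 (0.912).

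Immediate early genes, which are transcribed within minutes of a stimulus, were higher. Of 16 tested, 7 rose, 0 fell and 9 did not pass; adjusted over the list alone, 10 rose. ZFP36, which destabilises cytokine mRNAs, rose by 1.63 ± 0.19, NR4A1, a nuclear receptor, by 1.33 ± 0.20 and IER3 by 1.07 ± 0.16 on the log2 scale (SE, n = 5 pairs; limma adjusted p = 0.00348, 0.0148 and 0.0148). The median change was 0.65, and the list's mean was above 0 in 5 of 5 pairs, between 0.51 and 0.79 (camera adjusted p = 1.85e-09; adjusted p = 0.0772 with an estimated correlation; fry adjusted p = 0.00171). All 3 were higher in 5 of 5 pairs. ZFP36 was called whichever pair was left out. NR4A1 missed the threshold without pair 1 (0.0528) or pair 5 (0.0869) and with the mean of its probe sets (0.82, adjusted p = 0.0866), 1 of which gave 0.09, and IER3 without pair 2 (0.0591) or pair 5 (0.0556).

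Genes of the unfolded protein response, which is set off by misfolded protein in the endoplasmic reticulum, were higher. Of 10 tested, 4 rose, 0 fell and 6 did not pass; adjusted over the list alone, 8 rose. The chaperone gene HSPA5 rose by 1.19 ± 0.18, the stress transcription factor DDIT3 by 1.43 ± 0.24 and HERPUD1, a component of protein degradation at the reticulum, by 0.88 ± 0.18 (SE, n = 5 pairs; limma adjusted p = 0.0148, 0.0210 and 0.0415). The median was 0.66 and the mean was above 0 in 5 of 5 pairs (camera adjusted p = 8.18e-06; adjusted p = 0.364 with an estimated correlation; fry adjusted p = 0.0619). All 3 were higher in 5 of 5 pairs. HSPA5 lost its call without pair 1 (0.0588) or 5 (0.0866), DDIT3 without pair 1 (0.0639), 2 (0.0815) or 5 (0.107), and HERPUD1 without pair 1 (0.0750), 2 (0.164), 3 (0.0675) or 5 (0.131) and in pairs 5 and 6 alone (0.58, adjusted p = 0.272). Of 11 heat shock genes, 0 passed over all genes and 4 rose adjusted over the list alone, with HSPD1 at 0.60, HSPE1 at 0.62 and HSPB1 at 0.33, and a median of 0.27 (camera adjusted p = 0.00771; adjusted p = 0.364 with an estimated correlation; fry adjusted p = 0.142). The heat shock median was 0.10 with array weights, 0.45 in pairs 1, 2 and 3 alone, 0.15 without pair 2 and 0.14 without pair 3, where the call was lost (adjusted p = 0.0523), and the call was also lost in pairs 5 and 6 alone, where the median was 0.01 (adjusted p = 0.495).

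Genes of glycolysis and the response to low oxygen were higher. Of 21 tested, 3 rose, 0 fell and 18 did not pass; adjusted over the list alone, 7 rose. LDHA, which makes lactate from pyruvate, rose by 1.58 ± 0.23, the growth factor VEGFA by 1.01 ± 0.16 and NDRG1 by 0.82 ± 0.15 (SE, n = 5 pairs; limma adjusted p = 0.0140, 0.0167 and 0.0325). All 3 were higher in 5 of 5 pairs. LDHA lost its call without pair 5 (0.0761), VEGFA without pair 1 (0.0588) or 5 (0.0889), and NDRG1 without pair 1 (0.0639), 2 (0.110), 3 (0.0632) or 5 (0.132). The list's median was 0.24, with 5 of 5 pairs above 0 (camera adjusted p = 1.87e-04; adjusted p = 0.364 with an estimated correlation; fry adjusted p = 0.128). It was 0.15 without pair 2, 0.16 with array weights, 0.12 with the mean of a gene's probe sets, 0.41 in pairs 1, 2 and 3 alone and 0.06 in pairs 5 and 6 alone. Of 16 matrix remodelling genes, MMP10, VEGFA and the protease gene ADAM8 (0.90 ± 0.18, adjusted p = 0.0413) rose, also when adjusted over the list alone, and 13 did not pass. ADAM8 lost its call without pair 1 (0.129), 2 (0.162), 3 (0.0615) or 5 (0.158). The median was 0.31, with 4 of 5 pairs above 0 (camera adjusted p = 0.00172; adjusted p = 0.369 with an estimated correlation; fry adjusted p = 0.142), and it was 0.18 without pair 2 and 0.17 in pairs 5 and 6 alone.

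Markers of monocytes and macrophages were lower after challenge. Of 15 tested, VSIG4 and CD68 fell, 0 rose and 13 did not pass; adjusted over the list alone, 8 fell. C1QB, a complement component made by macrophages, had a log2 change of -1.53 (adjusted p = 0.0601). The median was -0.95, and the list's mean was below 0 in 5 of 5 pairs, from -2.05 in pair 1 and -1.33 in pair 6 to -0.15 in pair 3; without pair 1 the median was -0.60 (camera adjusted p = 1.82e-05 over all 5 pairs; adjusted p = 0.364 with an estimated correlation; fry adjusted p = 0.143). CD14, a monocyte receptor for bacterial lipopolysaccharide chosen after its values were seen, ran the other way at 0.92 and did not pass (adjusted p = 0.250). The size of the list's fall went in part with RNA quality, and less clearly with brightness. The log2 GAPDH 3' to 5' ratio rose most in pairs 1 (1.08 to 1.65) and 6 (0.91 to 1.30) and fell in pair 3 (1.84 to 1.14). For ACTB the ratio rose most in pair 2 (1.77 to 2.11). Pairs 1 and 6 were also those with a dimmer array after challenge. In pair 1 the trimmed mean hardly differed (43.7 before, 42.5 after), while in pair 6 it went from 153 to 117. VSIG4 lost its call without pair 1 (0.142), 2 (0.168), 5 (0.0869) or 6 (0.0846), and CD68 without pair 1 (0.128), 2 (0.176), 5 (0.135) or 6 (0.0790).

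MHC class II genes, which present antigen and are abundant in macrophages, moved with the macrophage markers. Of 9 tested, 0 passed over all genes and 6 fell adjusted over the list alone. HLA-DMB was at -0.77, HLA-DPA1 at -0.78 and HLA-DQB1 at -0.74 (limma adjusted p = 0.0657, 0.105 and 0.113), and HLA-DQB1 at -0.20 with the mean of its probe sets. All 9 log2 changes were below 0, with a median of -0.62, and the list's mean was below 0 in 4 of 5 pairs, all but pair 3 (camera adjusted p = 1.92e-05; adjusted p = 0.369 with an estimated correlation; fry adjusted p = 0.158). At an unadjusted p of 0.05, limma gave 7 of the 9 as lower.

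Ribosomal protein genes were slightly lower as a group. None of 29 on the list passed, over all genes or adjusted over the list alone, and 27 of the 29 log2 changes were below 0. RPS19, RPL10A and RPL8 had log2 changes of -0.31, -0.31 and -0.32. The median was -0.20, in 5 of 5 pairs below 0 (camera adjusted p = 1.44e-05; adjusted p = 0.446 with an estimated correlation; fry adjusted p = 0.142). RPS28, a gene of the small ribosomal subunit outside the list and chosen after its values were seen, fell by 0.51 ± 0.10 in 5 of 5 pairs (SE; limma adjusted p = 0.0415), but was not called with any 1 pair left out (0.0531 to 0.165). The list's median was -0.12 without pair 1 and -0.11 with quantile normalization, and in pairs 5 and 6 alone the adjusted p was 0.0815. The median stayed below 0 under every scaling tried, between -0.25 and -0.10 over all alternatives.

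Among epithelial cell types, markers of club and secretory cells, which make the fluid of the airway lining, were lower as a group. None of 13 passed, over all genes or adjusted over the list alone, with PIGR, the transporter of secreted antibodies, at -0.54, ALDH3A1 at -0.48 and CYP4B1 at -0.43. The median was -0.23, with 4 of 5 pairs below 0 (camera adjusted p = 0.00598; adjusted p = 0.406 with an estimated correlation; fry adjusted p = 0.163). The call was lost without pair 5 (adjusted p = 0.0519), without the subject block (0.130) and with the subject as a random block (0.0835). Of 9 basal cell genes, S100A2 (1.30, adjusted p = 0.0282) and the laminin gene LAMB3 (0.83, adjusted p = 0.0494) rose and KRT15 fell, each in 5 of 5 pairs, while 6 did not pass; adjusted over the list alone, 3 rose and 1 fell (median 0.19, camera adjusted p = 0.225). Of 11 squamous and wound-edge genes, KRT13 (0.77, adjusted p = 0.0176) and SERPINB3 (0.96, adjusted p = 0.0413) rose in 5 of 5 pairs, also adjusted over the list alone, KLK11 was at -0.32 and 9 did not pass, and the list missed the threshold (median 0.21, 5 of 5 pairs above 0, camera adjusted p = 0.0553). It passed without pair 2 (0.0367) or pair 5 (0.0242), with the mean of a gene's probe sets (0.0188) and in pairs 5 and 6 alone (0.0461). Without pair 6 its median was 0.06 (0.176) and without pair 1 it was 0.12 (0.0505). S100A2 lost its call without pair 1 (0.0639), 3 (0.0632) or 5 (0.102), LAMB3 without pair 1 (0.152), 2 (0.179), 5 (0.177) or 6 (0.0846), KRT15 without pair 1 (0.0642), 2 (0.0874), 3 (0.0655) or 5 (0.0507), KRT13 without pair 1 (0.0613), 2 (0.0731) or 5 (0.102), and SERPINB3 without pair 1 (0.0613), 2 (0.104), 3 (0.108) or 5 (0.102).

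Goblet cell and mucus genes went both ways. Of 13 tested, TFF1, a peptide of mucus, rose by 1.85 ± 0.38, in 4 of 5 pairs (limma adjusted p = 0.0432), and 12 did not pass; adjusted over the list alone, 5 rose and 3 fell. CEACAM5 and AGR2 had log2 changes of 0.78 and 0.72 (adjusted p = 0.0557 and 0.0736). A second CEACAM5 probe set, with a mean signal below the filter, went the other way at -0.51. The list was not called (median 0.14, camera adjusted p = 0.225), but it was without pair 3 (adjusted p = 0.0281), while without pair 1 its median was -0.04 (0.614). TFF1 lost its call without pair 1 (0.140), 2 (0.176), 5 (0.155) or 6 (0.0643). Chosen after its values were seen, the mucin gene MUC5AC had a log2 change of -0.10 ± 0.14. Of 8 ciliated cell genes, 0 passed on either adjustment, DNAH7 and IFT88 were at -0.49 and -0.32, SPA17 at -0.15 (median -0.16, camera adjusted p = 0.158; -0.06 without pair 5 and -0.10 without pair 2). Of 6 submucosal gland genes, 0 passed over all genes and 1 fell adjusted over the list alone, with LYZ, which encodes lysozyme and is also abundant in macrophages, at -1.16, AQP5 at -0.41 and PIP at 0.24 (median -0.09, camera adjusted p = 0.475). Of 15 cell junction genes, 0 passed on either adjustment, with JUP, PKP3 and CLDN8 at 0.41, 0.45 and -0.52 (median 0.08, camera adjusted p = 0.355).

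Genes tied to allergic inflammation showed no shift past the threshold as lists. Of 23 listed genes of the interleukin-13 response of airway epithelium, 13 were on the array and only 7 were tested. Of the 7, 0 passed over all genes, and adjusted over the list alone CEACAM5 rose (its probe set below the filter gave -0.51) and CLCA1 fell, at -0.97. NOS2, which makes nitric oxide, was at -0.38, with another probe set above the filter at 0.11, and the list's median was -0.26 and its mean -0.06 (camera adjusted p = 0.800). Over all alternatives the median ran from -0.30 to 0.10. Below the signal filter, and chosen after their values were seen, SOCS1, an inhibitor of cytokine signalling, was at 1.43 and SLC26A4, an anion transporter, at 1.39, without passing (limma adjusted p = 0.0689 and 0.173 with no filter). The remaining members below the filter showed no such rise, with SERPINB10 at 0.37, IL13RA2 at 0.01, DPP4 at -0.14 and HSD3B1 at -0.31. Of 9 type 2 cytokines and receptors, 0 passed over all genes and 1 rose adjusted over the list alone, IL4R at 0.73, with IL2RG and STAT6 at 0.31 and 0.15 (median 0.21, camera adjusted p = 0.0745). That list was called without pair 3 (adjusted p = 0.0281), with the filter at the 60th percentile (0.0469) and without probe sets ending in _x_at and _s_at (0.0499), and without pair 5 its adjusted p was 0.214. Chosen after their values were seen, the type 2 cytokines IL13 and IL5 had log2 changes of -0.03 ± 0.24 and 0.36 ± 0.33. Of 11 CC chemokines, CCL3 rose by 1.28 ± 0.26 in 4 of 5 pairs (limma adjusted p = 0.0422) and 10 did not pass; adjusted over the list alone, 4 rose and 2 fell. CCL3 lost its call without pair 1 (0.118), 2 (0.175), 3 (0.105) or 5 (0.158). CCL4 was at 1.97 and CCL5 at -0.67 (adjusted p = 0.0518 and 0.0593; median 0.22, camera adjusted p = 0.344). That median was 0.13 without pair 1, 0.01 without pair 2, 0.39 without pair 3 and 0.01 without the filter. Of 14 eicosanoid pathway genes, 0 passed over all genes and 4 fell adjusted over the list alone, with PTGDS, LTA4H and PTGER4 at -0.73, -0.81 and -0.73. The PTGDS probe set belongs to a gene family, and another with signal above the filter gave 0.06. The median was -0.18 with 5 of 5 pairs below 0 (camera adjusted p = 0.0595), and the list was called without the subject block (0.0437) and without pair 2 (0.0432), pair 3 (0.0327) or pair 5 (0.0494), while without pair 1 its median was -0.11 (0.183).

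Of 20 interferon response genes, ISG20 rose by 1.03 ± 0.16 in 5 of 5 pairs (limma adjusted p = 0.0156), also adjusted over the list alone, and 19 did not pass, with GBP1 at 0.79 and IFI6 at -0.45 (median 0.22, 4 of 5 pairs above 0, camera adjusted p = 0.0595). The list was called without pair 2 (0.0142), pair 5 (0.0465) or pair 6 (0.0169), without the filter (0.00499), in pairs 1, 2 and 3 alone (0.00545) and with the GAPDH ratio as a covariate (0.0156). Without pair 3, whose mean was 0.71, the median was 0.04 (0.918), and in pairs 5 and 6 alone it was -0.05 (0.891). ISG20 lost its call without pair 1 (0.0588) or 5 (0.0799). Of 12 proliferation genes, 0 passed over all genes and 1 fell adjusted over the list alone, AURKA at -1.13, with MCM5 at -0.50 and MCM2 at -0.25. The median was -0.19 with 5 of 5 pairs below 0 (camera adjusted p = 0.0595; fry adjusted p = 0.00171). The list was called without the intensity trend (0.0348), with all probe sets (0.0448) and with the GAPDH ratio as a covariate (0.0412). Of 7 glucocorticoid response genes, SGK1 (adjusted p = 0.0403, 5 of 5 pairs) and CEBPD (adjusted p = 0.0494, 4 of 5 pairs) rose by 0.86 each and TSC22D3 fell, also adjusted over the list alone, and 4 did not pass; the median was -0.04, the mean 0.01 and camera's direction up (adjusted p = 0.881). With any 1 pair left out, SGK1 was not called (adjusted p from 0.0731 without pair 2 to 0.120 without pair 1), CEBPD only without pair 6 (0.121 to 0.185 without pairs 1, 2, 3 or 5), and TSC22D3 not without pair 1 (0.0639), 2 (0.0710) or 5 (0.0869). Of 8 EGF receptor ligands and receptors, HBEGF, a growth factor of wound repair, rose by 1.13 ± 0.21 in 5 of 5 pairs (limma adjusted p = 0.0333; without pair 1, 2, 3 or 5 it was 0.0941, 0.110, 0.0796 or 0.131), and 7 did not pass; adjusted over the list alone 1 rose and 1 fell, ERBB2 at -0.51, with EGFR at -0.35. Its median was -0.11, its mean 0.01 and camera's direction down (adjusted p = 0.881).

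Of 26 oxidative phosphorylation genes, NDUFV2 rose by 0.61 ± 0.12 in 5 of 5 pairs (limma adjusted p = 0.0368; without pair 1, 2, 3 or 5 it was 0.123, 0.118, 0.0728 or 0.146) and 25 did not pass; adjusted over the list alone 2 rose, with CYCS at 0.77 and NDUFB8 at -0.27 (median -0.08, camera adjusted p = 0.534). Of 13 oxidant and xenobiotic defence genes, 0 passed over all genes and 1 fell adjusted over the list alone, with AKR1C3, TXNRD1 and NQO1 at -0.59, 0.35 and -0.38 (median -0.06, camera adjusted p = 0.534). Of 10 complement and coagulation genes, 0 passed over all genes and 2 fell adjusted over the list alone, with CFD, SERPING1 and PROS1 at -0.58, -0.69 and -0.52 (median -0.09, camera adjusted p = 0.225).

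Lists of other immune and stromal cells were not called. For T cells, 0 of 11 passed on either adjustment, with CD4, CD3E and CD3D at -0.57, -0.33 and -0.30, and both other CD4 probe sets at -0.01 and 0.16 (median -0.16, camera adjusted p = 0.308). For NK and cytotoxic cells, 0 of 6 passed on either adjustment, with GNLY at -0.59, CST7 at 0.40 and GZMH at -0.28 (median -0.13, adjusted p = 0.787). For dendritic cells, 0 of 9 passed over all genes and 1 rose adjusted over the list alone, IL1R2 at 1.01, with FLT3 at -0.50 and CD83 at 0.37 (median 0.08, adjusted p = 0.383). For mast cells and basophils, 0 of 5 passed over all genes and 1 fell adjusted over the list alone, IL3RA, a subunit of the interleukin-3 receptor, at -0.99; CTSG was at 0.65 and CMA1 at -0.54, the median was 0.00, and the mean of -0.14 and camera's direction were down (adjusted p = 0.60). For smooth muscle, 0 of 6 passed on either adjustment, with LMOD1, TAGLN and MYLK at 0.61, 0.26 and -0.36, a median of -0.10, a mean of 0.02 and camera's direction up (adjusted p = 0.824).

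The other 7 lists had fewer than 5 members past the filter and were not tested as lists there. Where the alternatives without the filter or with all probe sets let camera test them, 0 were called (adjusted p from 0.166 for endothelial cells to 0.970 for red cells). None of their members passed over all genes. Of 2 eosinophil genes, PRG2, the granule major basic protein, was at 0.54 and IL5RA at -0.10. Below the filter, the eosinophil genes RNASE2, CLC and CEBPE were at 0.68, 0.54 and 0.17, and EPX and P2RY14 at -0.29 and -0.37. They did not pass (limma adjusted p from 0.352 to 0.826 with no filter). Of 4 B cell genes, CD37, CD79A and CD22 were at -0.63, -0.53 and 0.49, and 1 fell adjusted over the list alone. Of 4 plasma cell genes, IGHM, IGHG1 and IGKC were at 0.42, 0.31 and -0.18. Of 4 fibroblast genes, FBLN1, POSTN and COL1A1 were at -0.40, 0.75 and 0.08, with another COL1A1 probe set at -0.33, and 1 fell adjusted over the list alone. Of 4 endothelial genes, PECAM1, ENG and KDR were at -0.72, -0.62 and 0.62, and 1 rose and 2 fell adjusted over the list alone. Of 4 red cell genes, HBB, HBD and ALAS2 were at 0.10, -0.09 and -0.14, and of 2 platelet genes, ITGB3 and ITGA2B were at -0.19 and 0.02.

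**Figure D3:**
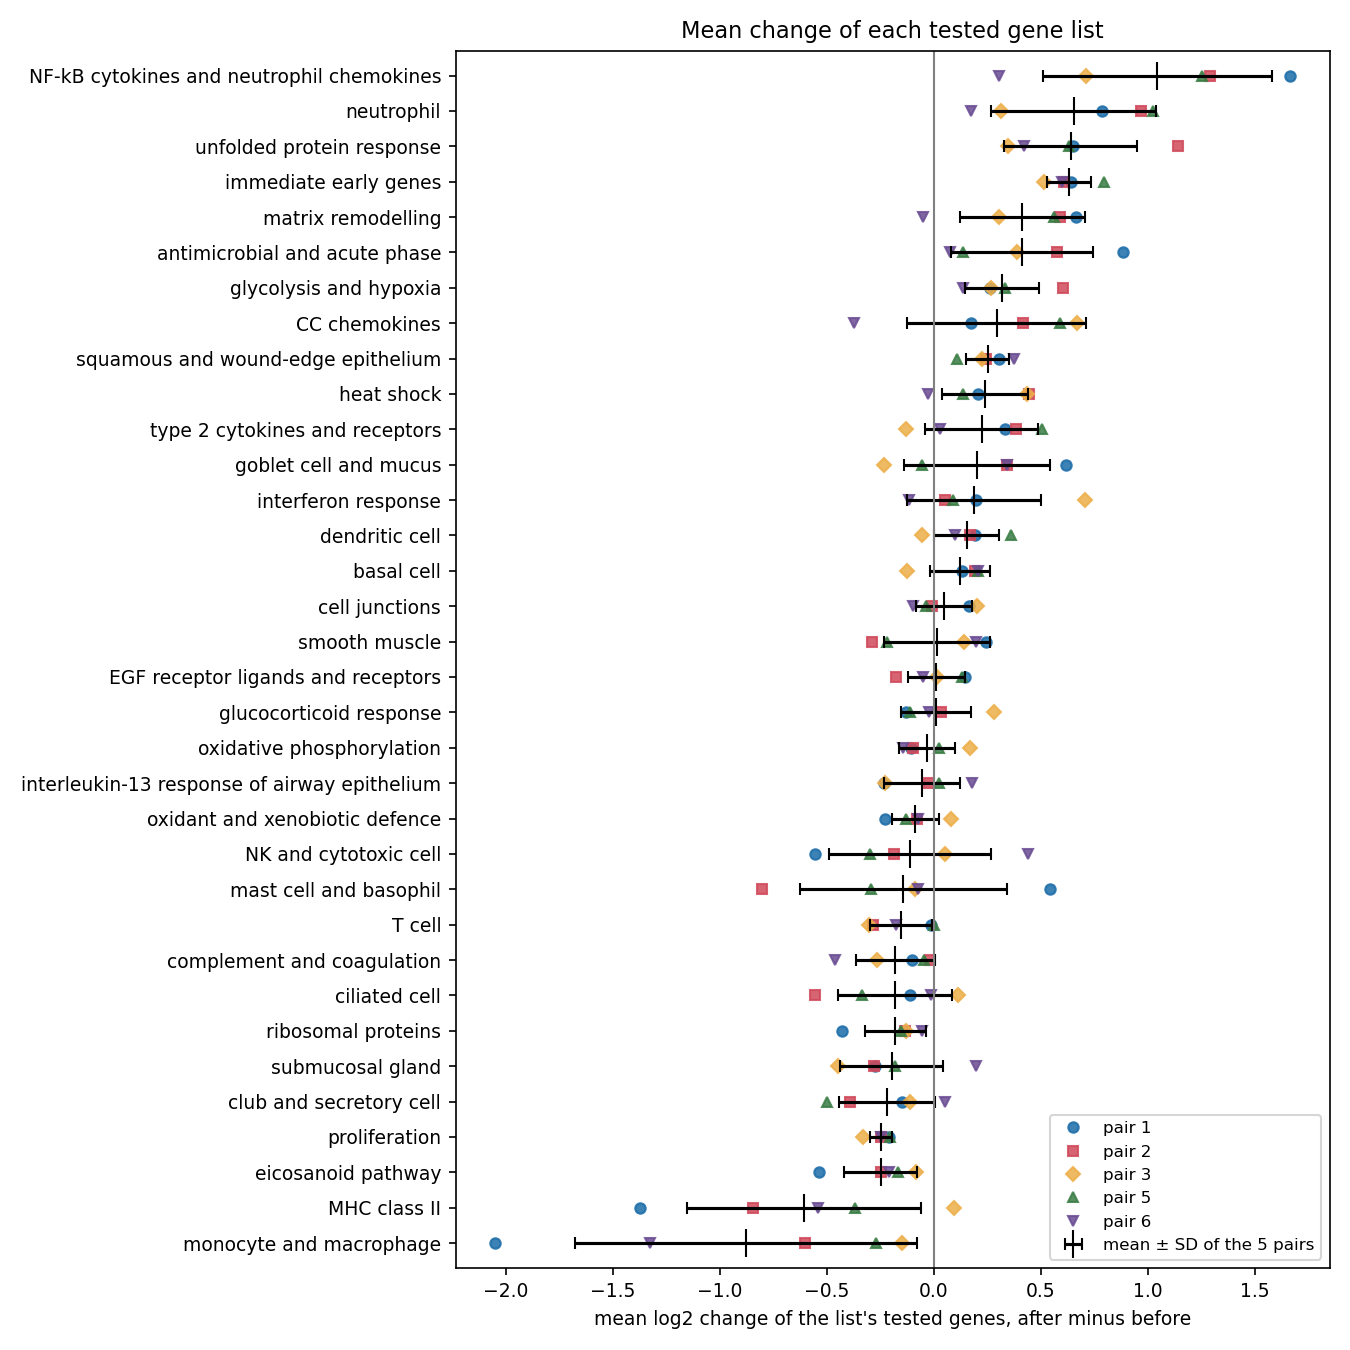
Mean log2 change, after minus before, of the tested genes of each of the 34 tested lists. Each point is 1 pair, and black bars are the mean ± SD of the 5 pairs. The monocyte and macrophage list spreads from -2.05 in pair 1 to -0.15 in pair 3, and the immediate early list from 0.51 to 0.79.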

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

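Among 76 groups of 5 values, 24 named genes, 11 called lists, the array brightness and the 2 RNA ratios before and after challenge, 4 held 1 sample far from the other 4 by Dixon's test, with a critical ratio of gap to range of 0.71. Chance gives about 1 in 20 such groups, so as many as these are within what chance gives.

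GCHFR, a regulator of GTP cyclohydrolase, had a log2 signal of 6.66 after challenge in pair 1, against 6.15 to 6.29 in the other pairs. The mean log2 signal of the immediate early genes, which respond within minutes to handling as well as to growth factors, was 7.41 before challenge in pair 1, against 6.79 to 6.95. For the unfolded protein response genes it was 8.60 after challenge in pair 2, against 8.12 or less. For the club and secretory cell genes it was 9.25 after challenge in pair 5, against 9.76 to 9.96. Leaving out pair 5 ended the call of the club and secretory list, while the immediate early and unfolded protein response lists were called whichever pair was left out.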

How the results depend on the processing

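The tests in pairs 1, 2 and 3 alone, in pairs 5 and 6 alone and with the GAPDH ratio as a covariate were chosen only after the results were seen. The 109 changed genes, 88 higher and 21 lower, were 31, 29 and 2 without the subject block of the paired design, with 11 lists called, where the club and secretory list gave way to the eicosanoid pathway. With the subject as a random block, 158 genes changed and 42 were lower, and 10 lists were called. Without the intensity trend in limma, 33 changed, 30 higher and 3 lower. With a pseudocount of 1 the lower genes were 13, with quantile normalization 13 and with median scaling 10. Without the filter 70 changed and 9 were lower, and with the mean of a gene's probe sets 67 and 8. Pairs 1, 2 and 3 alone gave 40 changed genes, 35 higher and 5 lower, and pairs 5 and 6 alone gave 51 higher genes. With single pairs left out, the changed genes ran from 10 without pair 5 to 108 without pair 6, the higher from 10 to 89 and the lower from 0 without pair 2 to 25 without pair 3. Without pair 2, limma gave 314 genes as lower at an unadjusted p under 0.05, and without pair 5 it gave 318. With the estimated correlation camera called 0 lists, and in the other settings 10 to 14. Over all settings, the 48 named genes kept their status, called or not called, in 864 cases, whatever the size of the change. A call was lost in 176 cases and gained in 10. The 11 called lists kept their call in 236 cases and lost it in 17. The direction did not turn in any of these cases. For the 12 higher and 12 lower genes named for changing the same way in all 5 pairs, leaving out pairs could not turn it. The subject block, the trend and robust eBayes do not alter the direction of a gene's change in these complete pairs. For those genes and settings the kept direction is therefore no support. Of the 23 lists not called, 20 had a median that moved by over 1.5 times or turned sign without at least 1 pair. The cause of the differences between settings was not tested.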

Other observations

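Of 18 tested genes that serum response factor drives, which build the actin cytoskeleton, 4 rose after challenge and 14 did not pass. This list of 24 genes and the next 1 were written after some members, these 4 among them, had been seen among the changed genes, so their list tests are no evidence that the group moved and are given as values only. Their p-values are adjusted over 38 lists, the 34 tested before and 4 added. The 4 were SRF, the factor itself (0.93), the adhesion gene VCL (1.01), the tropomyosin gene TPM4 (1.34) and the myosin light chain gene MYL9 (1.51), each in 5 of 5 pairs (limma adjusted p = 0.0146, 0.0145, 0.0190 and 0.0483). The median log2 change was 0.39, above 0 in 5 of 5 pairs (camera adjusted p = 1.94e-07; adjusted p = 0.182 with an estimated correlation). SRF lost its call without pair 1 (0.0549), 2 (0.0541) or 5 (0.0799), VCL without pair 2 (0.0541) or 5 (0.0799), TPM4 without pair 1 (0.0613), 2 (0.0747), 3 (0.0588) or 5 (0.111), and MYL9 without pair 1 (0.151), 2 (0.110), 5 (0.182) or 6 (0.0983). Genes of the ATF4 response, which supplies amino acids under stress, had a median of 0.37 in 24 tested genes, of which 3 rose and 21 did not pass, above 0 in 5 of 5 pairs (camera adjusted p = 6.03e-06; adjusted p = 0.339 with an estimated correlation). The 3 were MTHFD2, an enzyme of mitochondrial folate metabolism (1.38), the arginine transporter SLC7A1 (0.86) and DDIT3, each in 5 of 5 pairs and each seen before the list was written (limma adjusted p = 0.00720, 0.0494 and 0.0210). MTHFD2 lost its call without pair 5 (0.0507), and SLC7A1 whichever pair was left out, with adjusted p from 0.0588 without pair 1 to 0.191 without pair 5. Of 12 cholesterol synthesis genes, from a list written before their values were looked at, limma called 0, with 2 at an unadjusted p under 0.05, PMVK at -0.53 and IDI1 at 0.29 (median -0.05, camera adjusted p = 0.881).

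The cytokine gene IL6 and the collagenase gene MMP13 lay below the signal filter. With no filter, their log2 changes were 1.16 (limma adjusted p = 0.0314) and 0.97 (adjusted p = 0.0460).

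The 10 arrays were also split into groups of 5 in 100 ways, among them all 16 that part the 2 arrays of every pair. The other 84 keep some pairs whole, and a whole pair adds nothing to a fit with the subject as a block, so only the 16 can be compared with the real split. These 16 are too few for a share under 0.05. In the others of the 16 some pairs are turned round, so a true effect of challenge would add to their spread and also remain in part. Their counts of genes and lists are therefore not what no effect would give. Among the 16 the real split gave 109 changed genes, 88 higher and 21 lower, and the highest other gave 0. For the called lists the real split gave 11 and the highest other 14, with 3 of the 16 at 11 or more, the real one included. Over all 100 splits, 1 reached the count of changed genes, 1 that of higher genes, 3 that of lower genes and 12 that of lists, with highest others of 66, 42, 42 and 14.

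All tests of the macrophage pattern were chosen only after the result was seen. Markers of macrophages and MHC class II genes were lower after challenge, by a median of 0.95 and 0.62 on the log2 scale. With the GAPDH 3' to 5' ratio as a covariate the macrophage median was -0.76. The mean log2 ratio changed by only 0.09, so this could move the median little and leaves RNA degradation open. The list fell most in pairs 1 and 6, where that ratio rose from 1.08 to 1.65 and from 0.91 to 1.30. It fell least in pair 3, where the ratio fell from 1.84 to 1.14, though the ACTB ratio rose most in pair 2. Array brightness alone is argued against by 5 of 5 pairs below 0, though 3 were brighter and 2 dimmer after challenge. The dimmer pairs, 1 and 6, had the largest falls, at -2.05 and -1.33, so a part of brightness in the size is left open. But pair 1 was hardly dimmer (trimmed mean 43.7 before, 42.5 after), so for dimmer pairs both readings rest mainly on pair 6 (153 to 117). A smaller share of macrophages in the biopsies may account for the lower macrophage genes. But a second list of 28 tested macrophage and lysosome genes had a median of -0.21, between the values set for and against before it was computed. Of the 28, 0 passed and 5 were above 0, from APOC1 at -2.61 (limma adjusted p = 0.0654) to CTSZ at 0.64. At an unadjusted p under 0.05, 11 were lower and 1, CTSZ, was higher. For the list, the camera adjusted p was 5.89e-04, and 0.431 with an estimated correlation. Fewer macrophages and lower expression per cell cannot be told apart with these values.

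All tests of the next pattern were chosen only after the result was seen. The NF-kB and immediate early genes were higher after challenge, with medians of 0.91 and 0.65. Array brightness alone is argued against, since 5 of 5 pairs were above 0, though only pair 6 was clearly dimmer after challenge. Pair 6 had the smallest mean change of the NF-kB list, 0.30, so a part of brightness in its size is left open. The immediate early mean in pair 6 was 0.60, within the range of the other pairs. For RNA quality, the medians were 0.87 and 0.62 with the GAPDH ratio as a covariate. RNA of incoming neutrophils may account for part: without S100A8 and S100A9, 10 neutrophil genes had a median of 0.24, with a 95% bootstrap interval of -0.10 to 0.92, which reaches the 0.91 of the NF-kB list and leaves this open. Handling or the earlier bronchoscopy could also raise such genes, and with 0 groups given diluent alone in the labels this cannot be told apart from the allergen.

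The clock test below was chosen only after DBP and CRY1 were seen, and its reading was changed after its own value was seen. DBP, a clock-controlled transcription factor, fell by 1.32 and CRY1, a clock repressor, rose by 0.83 on the log2 scale (limma adjusted p = 0.0494 and 0.0477, 5 of 5 pairs each). CRY1 was not called with any 1 pair left out (0.0719 to 0.190), nor DBP without pair 1 (0.152), 2 (0.187), 3 (0.0750) or 5 (0.185). A candidate explanation is sampling at different times of day: the 3 other tested genes in phase with DBP had a median of -0.26, with NR1D2 at -0.70, PER2 at -0.26 and TEF at -0.08, and the 3 in antiphase one of -0.13, with NFIL3 at 0.94, CLOCK at -0.13 and NPAS2 at -0.33. By the rule set first, a median of the antiphase genes below 0 counted against this explanation, but 3 genes spread from -0.33 to 0.94 decide nothing, so it was left open and cannot be told apart from an effect of challenge.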
